A study of Glycine max with 6 samples.

How the data were processed

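RNA of untreated upper stem tissue from plants aged 15 days was labelled with Cy3 and Cy5 and hybridised to cDNA arrays, per the labels. Each array carried Williams 82 in 1 channel and PI194639 in the other. The series design gives 3 biological repeats with 2 technical repeats each, including dye swaps. The A arrays had Williams 82 in Cy3. Arrays 2B and 3B had it in Cy5, and 1B had it in Cy3 again with the channels exchanged, per the labels.

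The deposited values are log ratios of the 2 channels, taken here as log2. The base, the numerator, the centring and the normalization are not given in the sources used here, and fold values assume base 2. Array medians were 0.023 (1A), 0 (1B), -0.0039 (2A), 0 (2B), -0.0117 (3A) and 0 (3B). Exact zeros, which look like placeholders, were held by 195, 1432, 171, 1603, 1298 and 1807 probes in the same order, and 2947 probes had at least 1. They were kept as deposited. No value on any array was given for 555 of 19200 probes, and 1671 probes shared all their values with another probe. No spot intensities or background were used, so the signal behind a ratio is unknown.

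Gene names came from the platform annotation, which can be old. It gave 1 gene for 1158 probes, several for 13 and none for 18029, and probes with several genes were not named. Of 527 genes, 523 were found by gene identifier in the RefSeq table of assembly Glycine_max_v4.0, which was used for names, for the order of neighbouring genes and for whether genes lie on 1 chromosome, with no coordinates, and 172 have only a LOC number. The annotation gave no gene titles, so the lists were matched by symbol and synonym alone. The lists for lignin, germins, heat shock and sugar had no member.

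The rule set before the data were examined was to take the values as already turned if the A and B arrays of all replicates correlated positively, and to turn the B arrays if negatively. The replicates were mixed, so only 1B was turned. The A and B arrays of a replicate were then averaged, and the 3 replicate means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. Nothing says that the biological repeats were separate plants or pools. The dye effect was tested on the A minus B differences in the same way. Gene lists were tested on gene means with camera at a preset correlation of 0.01, for lists of at least 5 measured genes, and with an estimated correlation and fry as alternatives.

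Genes were named by a rule set before the data were examined. It took up to 12 genes each way with the largest mean among probes past the threshold, with the same sign on all measured arrays and 1 gene name, 1 probe per gene. It also took up to 4 members of each list by size, past the threshold or not, with at least 4 arrays measured. A gene named by the first part is given by its clone with the largest ratio among those that met that part, and a gene named by a list by its clone with the largest ratio, so the 2 can differ, as for LOC547820. Such a value is that of 1 clone, and clones of a gene can differ.

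The limma step was tested on simulated data of 18644 probes. It recovered 71 of 100 probes changed by a log2 ratio of 1 and 31 of 100 changed by 0.5, with 2 false calls. The list step, on 527 genes with the flavonoid list shifted, found that list in 100 of 100 runs, and 4 of 100 runs called a list that was not shifted.

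Alternatives planned beforehand covered how technical arrays are combined, array A or B alone, leaving out each replicate or array 1B, scaling between arrays, missing values, the moderation and the threshold. Added after seeing the data were exact zeros as missing, identical probes counted once, 1B with its deposited sign, the channel 2 over channel 1 reading, a dye term from the labels (for the dye effect too), and the gene lists without 1B or on A or B arrays alone. The test of the channel reading was also changed after a first result. It compared the difference between replicates 2 and 3 on the A arrays with that on the B arrays, at first over all probes and over the 259 that passed, where r was -0.199. Probes that pass are selected for a small difference between replicates, which pushes that r below 0, so the 200 probes with the largest shared log ratio took their place. The bound for these was first set at r above 0, which 0.0911 met, and was then tightened to an interval above 0, which it did not meet.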

Results

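Transcript levels in the upper stem of untreated soybean plants (Glycine max) aged 15 days were compared between 2 genotypes, the cultivar Williams 82 and the plant introduction PI194639, on spotted cDNA arrays with 2 channels. Each of 6 arrays carried both genotypes, 1 in each channel, and the arrays formed 3 biological replicates of 2 technical arrays, A and B. The series concerns the early response of the stem to the fungus Sclerotinia sclerotiorum, and these arrays hold the untreated starting point. Of 19200 probes, 18644 had a value in every replicate and were tested, and 17924 had a value on all 6 arrays. The number of arrays limits the precision, and the median SD between the 3 replicates was 0.11 on the log2 scale.

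The first question was how the deposited ratios run. As deposited, the 5 arrays other than 1B correlated with one another at r = 0.19 to 0.54 across probes. Array 1B correlated with each of them at r = -0.356 to -0.233, and at r = -0.346 with its partner 1A. By the labels, 1B carried the same dye on each genotype as 1A, whereas 2B and 3B carried the dyes the other way round. The sign of 1B was turned before averaging. Which genotype is the numerator is not settled by the labels or the values, so ratios are given as negative or positive with no genotype, and turning every sign exchanges the negative and positive counts. The correlations also allow another reading, in which each value is channel 2 over channel 1. What the A and B arrays share would then be a dye effect, and under that reading 0 probes passed limma's test, with 2006 at an unadjusted p under 0.05, although replicate 1 then mixes genotype and dye. All differences below hold under the first reading only, in which every array but 1B already has its ratio turned to 1 order of the genotypes.

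**Figure D1:**
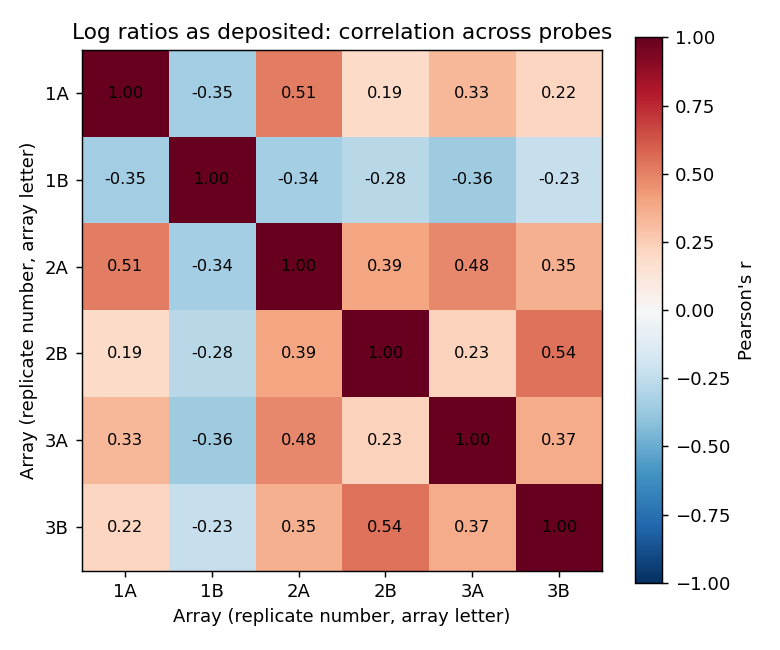
Pearson's r across probes between the log ratios of the 6 arrays as deposited, with arrays on both axes and r as colour and number. Array 1B lies between -0.36 and -0.23 with every other array, while the 5 others lie between 0.19 and 0.54.

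The 3 biological replicates, each the mean of its A and B arrays, correlated across probes at Pearson's r = 0.454 for replicates 1 and 2, 0.422 for 1 and 3, and 0.560 for 2 and 3. Spearman's rho was 0.278, 0.283 and 0.346 in the same order. Probes are not independent replicates, so no p is given.

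Clones of the lipoxygenase genes LOC547835, LOXB1, LOX7 and VLXC, and of the vegetative storage protein genes LOC547820 and VSPA, passed with negative ratios. Lipoxygenases add oxygen to polyunsaturated fatty acids. LOC547835, also called LOX1.4, had a mean log2 ratio of -1.82 ± 0.20 (SD, n = 3 replicates; limma adjusted p = 0.00392), a 3.54-fold difference between the genotypes. The lipoxygenase LOXB1, also called VSP94, stood at -1.48 ± 0.12 (limma adjusted p = 0.00392) and LOX7 at -1.44 ± 0.30 (limma adjusted p = 0.00994). A clone of LOC547820, also called VSPB, stood at -1.51 ± 0.53 (limma adjusted p = 0.0282), while its clone with the largest ratio, -1.65 ± 0.80, did not pass (limma adjusted p = 0.0565). A clone of VSPA stood at -0.84 ± 0.27 (limma adjusted p = 0.031). Averaged over their clones, neither LOC547820 nor VSPA passed (limma adjusted p = 0.0877 and 0.0509). On the positive side a clone of the asparagine synthetase gene AS2 had the largest ratio of a named gene, 1.43 ± 0.13 (limma adjusted p = 0.00392), or 2.69-fold. The 7 clones of AS2 ran from 0.22 to 1.43, and 4 of them passed.

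In all, 259 of 18644 probes passed at a false discovery rate of 0.05, 148 negative and 111 positive, and 55 of them had a gene name. Negative ratios made up 57.1% of the 259 (95% exact binomial interval 50.9 to 63.3, which treats probes as independent). An absolute log2 ratio of at least 1 was reached by 63 of them, 38 negative and 25 positive, and 248 had the same sign on every array that measured them. Of the 527 named genes averaged over clones, 90 had an unadjusted limma p under 0.05 and 17 passed, 12 negative and 5 positive. The negative genes include P89, whose call rests on a clone with the same values as a LOXB1 clone, so those values are counted under both names. The count moved with single replicates and arrays: it was 316 without replicate 1, of which 189 were among the 259, 0 without replicate 2 (1830 probes at an unadjusted p under 0.05), 133 without replicate 3, 99 without array 1B, 60 on the A arrays alone and 0 on the B arrays alone (2531 at an unadjusted p under 0.05). With 1B as deposited it was also 0 (1352 at an unadjusted p under 0.05), as it was with a one-sample test on each probe alone (1908), and it was 529 when exact zeros were treated as missing.

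The list fixed for jasmonate and ethylene matched 11 measured genes, 7 of them lipoxygenases, 2 allene oxide synthases and 2 vegetative storage proteins, with no ethylene gene among them. At gene level 3 passed, LOC547835, LOX7 and LOXB1, all negative, and 8 did not; adjusted over the list alone, 8 passed. The list lay lower than other genes in camera with a preset correlation (median log2 ratio -0.28, adjusted p = 8.17e-07). That call was lost with the correlation estimated from the data (adjusted p = 0.495 with an estimated correlation). In fry, which tests the list against no change and not against other genes, the adjusted p was 0.0728. Of 45 clones of these genes, 15 passed negative and 1 positive. Of the 7 clones of LOC547835, 6 passed with negative ratios, and the other stood at 0.16. The 8 clones of LOXB1 ran from -1.48 to 0.41; 4 passed negative and the clone at 0.41 passed positive. Of the 3 clones of LOX7, 2 passed with negative ratios, and the other stood at -0.30. No clone of LOX1.1, LOX2, LOX3 or VLXB passed. The vegetative storage protein list, which shares its 3 genes with this one, had 1 gene called negative, the lipoxygenase LOXB1, and 3 adjusted over the list alone. A clone of VLXC, a lipoxygenase outside the list, stood at -1.14 ± 0.47 (limma adjusted p = 0.044). Its other clone lay at -0.30, and averaged over both VLXC passed at -0.72 (limma adjusted p = 0.0218).

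**Figure D2:**
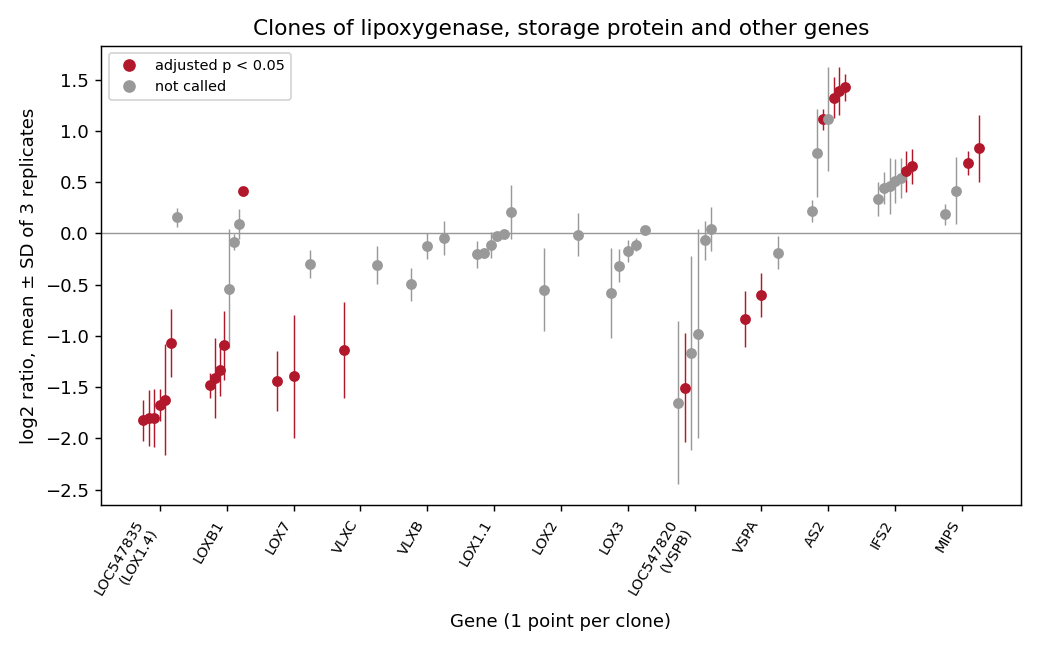
Mean log2 ratio of each clone (points, bars ± SD over 3 replicates) by gene, with clones past an adjusted p of 0.05 in red and the others in grey. Clones of 1 gene can differ, as LOXB1 shows with values from -1.48 to 0.41, while all 7 clones of AS2 and of IFS2 lie above 0.

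Genes of flavonoid branches lay on both sides. IFS2, an isoflavone synthase, stood at 0.65 ± 0.17 (limma adjusted p = 0.0279), and all 7 of its clones had positive ratios, 2 of which passed. IFS1 was measured at 0.67 ± 0.46 and did not pass (limma adjusted p = 0.125). The flavonoid and isoflavonoid list held 15 genes, of which 1 passed, IFS2, and 1 adjusted over the list alone; its camera adjusted p was 0.86, with a median of -0.03 and a mean of 0.01. The clones with the largest ratio of IFR2 and CHR1 were at -0.32 and -0.31, neither past the threshold. Averaged over clones, these genes were at -0.23 and -0.08. ANS2, an anthocyanidin synthase, stood at -0.94 ± 0.19 (limma adjusted p = 0.0143). In the anthocyanin list 1 of 3 genes passed, ANS2, and 2 adjusted over the list alone. The clone of F3H with the largest ratio was at -0.63 ± 0.35 (limma adjusted p = 0.0873), and DFR1 was at -0.24. The 3 genes of the phenylpropanoid list, 4CL2, 4CL3 and 4CL4, lay between -0.20 and 0.04 and none passed.

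Of 4 protease inhibitor genes, 1 passed, and 1 adjusted over the list alone. It was KTI-2, a Kunitz trypsin inhibitor, at -1.09 ± 0.32 (limma adjusted p = 0.0235), while KTI3 was at -0.28, BBI at 0.11 and D-II at 0.12. The single pathogenesis-related gene, PR-10, was at 0.16 ± 0.39. Of 23 oxidative stress and detoxification genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.86, direction up against a median of -0.02). A clone of the ascorbate peroxidase APX1 did pass, at 0.45 ± 0.07, while APX2 was at -0.45 ± 0.36, and clones of GSTU30 at 0.45 ± 0.40 and GSTF5 at 0.36 ± 0.07 did not. Averaged over clones, GSTU30 was at 0.14 and GSTF5 at 0.19. Of 41 stress transcription factors 1 passed, MYB138 at 0.47 ± 0.10, and 1 adjusted over the list alone (camera adjusted p = 0.263). The clones with the largest ratio of NAC1 and MYBZ2 were at 0.36 and -0.25, neither past the threshold, with gene means of 0.14 and -0.12. BZIP53B was at 0.53 ± 0.73 without passing, and 4 of its 6 values were exact zeros, which look like placeholders.

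Markers of other tissues were read beside these. Among 6 seed storage protein genes 0 passed, and 1 adjusted over the list alone (camera adjusted p = 0.36). A clone of the glycinin gene GY4 passed at -0.66 ± 0.23 (limma adjusted p = 0.0436), while GY2 was at -0.17, GY1 at -0.11 and CG-1 at -0.11, with exact zeros as 3 of the values behind CG-1. Of 2 nodule genes 0 passed at gene level and 2 adjusted over the list alone, in opposite directions. Adjustment over so short a list is mild, and 90 of 527 named genes had an unadjusted limma p under 0.05. A clone of NOD33 passed at -0.96 ± 0.38, and UR9 was at 0.19. In the cell wall list 0 of 2 genes passed and 1 did adjusted over the list alone, with XTH1 at -0.36 and EXP1 at -0.05.

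No gene of the lists for photosynthesis, ribosomal proteins, water and cold stress, circadian clock, or histones, cyclins and tubulins passed over all genes or adjusted over the list alone. Their members with the largest ratios were PSAD at 0.25, CAB3 at 0.17, LOC547819 at -0.01, RPL37 at 0.17, RPL2 at 0.10 (4 of 6 values exact zeros), PIP2-6 at -0.25, MAT1 at 0.20, LEA5 at 0.03, LHY at -0.01, SAT1 at -0.01 and TUBB3 at -0.08. SAT1 entered the circadian clock list only through its synonym GIP3, and whether it belongs there was not checked. The list meant for resistance proteins matched only the ribosomal protein genes RPS6, at -0.13, and RPS13, at -0.09, and so says nothing of resistance proteins.

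Further named genes with large negative ratios were LOC732576 at -1.25 ± 0.14, LOC547648 at -0.94 ± 0.38 and GH at -0.90 ± 0.24. A clone named P89 stood at -1.41 ± 0.39, but its values were identical to those of a LOXB1 clone and the other 2 P89 clones lay at -0.06 and 0.06, so its name is uncertain. Positive ratios past the threshold were found for MIPS, an inositol phosphate synthase, at 0.83 ± 0.33, and the early light-inducible protein ELIP at 0.73 ± 0.20. This MIPS clone had no value on 1A, so its replicate 1 value, 1.198, is that of 1B alone with its sign turned. With 1B as deposited its mean was 0.03. Another MIPS clone passed at 0.69 ± 0.12. The other clone of ELIP lay at 0.07 and did not pass. Single clones passed of PGLCAT8 at 0.55 ± 0.09, the receptor-like kinase SARK at 0.47 ± 0.02, the stearoyl desaturase ACPD at 0.46 ± 0.04, SGR1 at 0.44 ± 0.04 and LOC547735 at 0.43 ± 0.03. None of these 5 genes passed when averaged over its 3 or 4 clones (limma adjusted p = 0.405, 0.0844, 0.3, 0.211 and 0.19), and the lowest clones of PGLCAT8 and SGR1 lay at -0.12 and -0.17. With MIPS, ELIP, AS2, IFS2, MYB138 and APX1, these made up the 11 genes that met the naming rule on the positive side. The largest ratios of all lay on probes with no gene name here, 2.43 ± 0.41 for Gm01493cDNA18kA, or 5.4-fold, 1.98 ± 0.32 for Gm02885cDNA18kA, -1.98 ± 0.70 for Gm00928cDNA18kA and -1.94 ± 0.38 for Gm03838cDNA18kA.

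**Figure D3:**
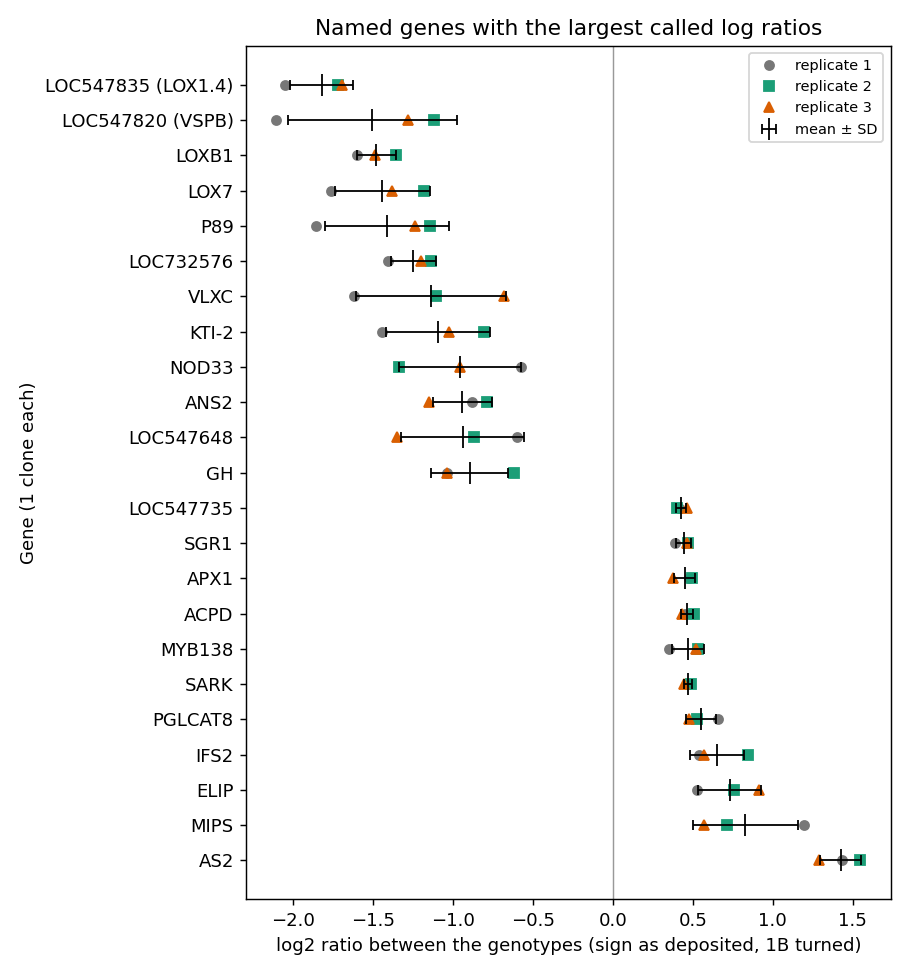
Log2 ratio of the 23 named genes with the largest ratios past the threshold, 1 clone per gene, with the 3 replicates as symbols and the mean ± SD as bars. The 12 negative genes, with P89 by a clone identical to a LOXB1 clone, run from -1.82 to -0.90 and the 11 positive genes from 0.43 to 1.43.

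The dye effect, taken as the difference between the A and B arrays within replicates, was tested on 17924 probes. With limma 0 probes passed, and 1741 had an unadjusted p under 0.05. In replicate 1 both arrays carried the same dye on each genotype by the labels, so a dye effect does not cancel in its mean and its A minus B difference holds none. Without replicate 1, 0 probes passed (2876 at an unadjusted p under 0.05). With a dye term taken from the labels, fitted to all 6 arrays with limma, 0 of 18644 passed (2036 at an unadjusted p under 0.05). Under the channel reading named above, the label-based term and the A minus B difference of replicates 2 and 3 would hold the genotypes, so these 2 counts of 0 would be those of the genotypes. Replicate 1 would then hold genotype and dye together in its mean and neither in its difference. Arrays of the same letter correlated at r = 0.541 (2B and 3B), 0.513 (1A and 2A), 0.477 (2A and 3A) and 0.331 (1A and 3A), against 0.393 for 2A and 2B and 0.370 for 3A and 3B, so in 3 of these 4 pairs arrays of different replicates were closer than the 2 arrays of 1 replicate. Array 1B is left out of these pairs. As deposited it correlated at -0.280 with 2B, -0.233 with 3B, -0.342 with 2A and -0.356 with 3A, all smaller in size than 0.370.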

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

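Every test in this part was chosen after the result was seen, except the count over turned replicates. Among 6 arrays, 1A stood apart with 1191 missing values, and with a median of 0.023. Of the probes missing on 1A, 636 had a value on at least 1 other array. Array 1B stood apart with a mean correlation of -0.312 with the others. For a single measure, chance flags about 1 in 20 such sets of arrays. More than 1 measure was examined, so the rate over all of them is higher and was not measured.

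Array 1B ran against the other arrays. After its sign was turned, its slope on the log ratio shared by replicates 2 and 3 was 0.716 (SE 0.0119). Under the first reading this argues against a failed or mixed array. If the shared part is dye effect, an array with mixed RNA could follow it too, so the slope does not then decide. An array with the dyes of 1A whose sign was turned as for a swap may account for the opposed values of 1B. The slope of turned 1B on the A minus B difference of replicates 2 and 3 was 0.317 (SE 0.0196), of the same sign as that of 1A, 0.444. That slope does not single out this account, because values deposited as channel 2 over channel 1 would give the same sign. The SEs of both slopes treat probes as independent. No biological explanation was tested, since both arrays of replicate 1 carry the same 2 genotypes.

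The log ratios shared by the A and B arrays have 2 readings, a genotype difference or a dye effect in values given as channel 2 over channel 1. If they were dye effect, differences between biological replicates would run opposite ways on A and B arrays. The correlation of those differences was 0.194 over all probes (95% interval 0.179 to 0.209), against that prediction. Over the 200 probes with the largest shared log ratio it was 0.0911, with an interval that includes 0 (-0.0483 to 0.227). Both intervals treat probes as independent and rest on replicates 2 and 3 alone, so they hold no spread over replicates. A dye effect that differs in strength between replicates could also give a value above 0. The readings cannot be told apart here, and with them it stays open whether the 259 probes differ between the genotypes or between the dyes.

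With the sign of 1 replicate turned, the highest count of probes past the threshold was 0, against 259 with none turned, and 1 of 4 settings gave as many as 259. So few settings allow no share under 0.05.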

How the results depend on the processing

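Several of these alternatives were chosen after seeing the data, as named in the processing summary, and the cause of a change was not tested unless stated. Against 259 probes, the count was 899 with all 6 arrays and replicate as a random block, 744 with arrays as independent, 532 with an array A or B term and the block, and 817 with a dye term from the labels and the block. These fits take 6 arrays from 3 biological replicates. The block did not lower the count, and its correlation in the fit with the dye term was -0.065. All of these counts therefore treat technical arrays much like independent replicates. The count was 498 after quantile normalization and 529 with exact zeros missing, which kept all 259. It was 99 without array 1B, 60 on A arrays and 0 on B arrays, and 0 to 316 leaving out 1 replicate, with 0 without replicate 2 (1830 at an unadjusted p under 0.05) and 133 without replicate 3. It was 0 with 1B as deposited, 0 as channel 2 over channel 1, and 0 with a one-sample test. By construction it was lower with an absolute log2 ratio of at least 1, 63, and at a false discovery rate of 0.01, 31. Median centring, scaling, probes on all 6 arrays, at least 2 replicates, robust moderation and identical probes counted once gave 259 to 383. The share of negative ratios was 56.1% to 61% under the 3 scalings, 51.2% with the dye term from the labels, and 66.7% on A arrays and without 1B. For the dye effect, limma called 1 probe after centring, 1 with exact zeros missing, 0 to 2 leaving out 1 replicate, with 2 without replicate 3, and 0 with a dye term from the labels (2036 at an unadjusted p under 0.05). The jasmonate and ethylene list had an adjusted p of 0.495 with an estimated correlation, and 2.05e-12 to 0.0334 in the other camera alternatives. Fry, which tests the list against no change and not against other genes, gave 0.0728. The stress transcription factor list reached 0.0375 with 1B as deposited, and 0.051 to 0.742 in its other alternatives. The other lists stayed above 0.05 throughout. Of 25 named probes past the threshold, 25 stayed past it after centring and with exact zeros missing, 22 without replicate 1, 14 without replicate 3, and 0 without replicate 2, on B arrays or with 1B as deposited. None changed sign where measured, but most were named only if all measured arrays had the same sign. For these, leaving out arrays or replicates could not change it. Of the 24 of them measured there, 13 stayed past it without 1B and 6 on A arrays. The log2 ratios of the 25 stayed at a median of 103% of the main value without replicate 2 (79.9% to 116%) and 103% on B arrays (71% to 126%). These probes were picked for passing on the same arrays, which favours ratios that agree between them. The sizes therefore do not show why the calls were lost there. With 1B as deposited the median fell to 57.8% (3.64% to 83.3%). Signal over background was not analysed here.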

Other observations

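The genes of this paragraph were chosen after their values were seen, since the naming rule did not reach them except F3H, and they hold under the first reading of the ratios only. PMM passed at -0.83 ± 0.30 and PGM at -0.76 ± 0.15, with 1 clone each (SD, n = 3 replicates). Of 2 clones each, 1 passed for XET1, at -0.87 ± 0.25 with the other at -0.73, and for PRX2B, at -0.38 ± 0.04 with the other at -0.28. The 2 clones of SHOOT1 and of EREBP1 differed: 1 passed at -0.55 ± 0.15 and -0.46 ± 0.02, and the others lay at -0.002 and 0.18. Averaged over clones, none of these 4 genes passed. Nor did GDH1, LOC547801 or F3H (limma adjusted p = 0.0879, 0.0818 and 0.0641). GDH1 had 4 clones, all negative, and 2 passed, at -0.49 and -0.44. Of 6 clones of LOC547801, 5 were negative and 3 passed. The 9 clones of F3H were all negative, from -0.63 to -0.03, and 1 passed, at -0.50. In all, 35 named genes had a clone past the threshold, 24 with a negative one and 12 with a positive one, LOXB1 being in both and P89 counted though its clone has the values of a LOXB1 clone.

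Clones of the chalcone synthase gene CHS1 lay close to 0, with 11 clones from -0.08 to 0.06, and those of the chalcone isomerase gene CHI1A ran from -0.12 to 0.24 over 10 clones. By gene order in Glycine_max_v4.0, LOX1.1, LOXB1 and LOX7 are direct neighbours, with gene means of -0.06, -0.68 and -1.05. VLXC and LOC547835 are neighbours on another chromosome.

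The negative lipoxygenases and vegetative storage proteins were weighed with tests chosen after the result was seen, except that of the dye. Cross-hybridisation of 1 lipoxygenase transcript stays open: the 5 of 9 VSPA and LOC547820 clones below -0.5 with 1 sign in all replicates are part of the pattern itself, the 13 lipoxygenase clones that span 0.756 were picked for passing with negative ratios, and neither count decides. A single linked region stays open too: the 6 genes lie on 3 chromosomes, but with cross-hybridisation open a clone's gene does not show which locus differs. Dye effect left in the mean would need a deviation of the A and B arrays from their mean as large as the mean itself, and the median sizes were 0.177 and 1.44; the bound, set beforehand, was met, but it takes the first reading for granted, and after the result was seen it was decided that it excludes nothing while the channel reading is open. A genotype difference in this group therefore remains a hypothesis beside the dye.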
